A study of Bos taurus with 6 samples.

How the data were processed

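The arrays measured RNA of white blood cells from heifers of the Sanhe breed, a Chinese dual-purpose cattle breed, with an Affymetrix bovine array read in a single colour after biotin labelling. The labels put 3 arrays after cold exposure (numbered 1, 2 and 3) and 3 before it (numbered 4, 5 and 6). The study's design text states that the 6 RNA samples came from 3 animals drawn from 30 heifers, each sampled at both times. It does not say which samples share an animal, so no pairing entered the main comparison. The p-values therefore treat the 6 arrays as separate although pairs of them share an animal.

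The deposited values are probe set intensities on a linear scale, 1 column per array, and GCOS and RMA are named without versions in the submitters' processing notes. RMA is a procedure that corrects background, aligns the distributions of the arrays and summarises the probes of a set. The genome build and any filter on probe sets are not given in the sources used here. The table held 12763 probe sets and 0 control probe sets. The intensities ran from 3.91 to 18225, and the array medians differed by up to 0.24 on the log2 scale. The medians of the deposited intensities on the log2 scale were 7.36, 7.49 and 7.25 after cold and 7.41, 7.36 and 7.44 before. All tests used the log2 of these values with no further normalization, no pseudocount and no filter on dim probe sets. The precision is limited by the number of arrays. Detection calls, which would tell signal from background, were not used here.

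Probe sets were named through the platform annotation. A single gene symbol belonged to 8125 probe sets, several symbols to 56, and 4582 had none and stay unnamed here. Of the 8125, 8109 matched a current gene identifier in the RefSeq gene table of the assembly ARS-UCD2.0, which was used for names and gene spans only, and 0 symbols changed. These probe sets stand for 6337 genes, of which 1419 had more than 1 probe set. A gene was represented by the probe set with the highest mean over all 6 arrays.

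Each probe set was compared between groups, after minus before cold, with limma 3.58.1 in R 4.3.3, by a linear model with moderated variance and no block, two-sided, over all probe sets with Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. Errors of a change are the standard errors (SE) of this model, and errors of a group mean are standard deviations (SD) over 3 arrays. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1. Before the data were examined, 33 gene lists were fixed for blood cell types and for cold, stress, immune and metabolic responses. Lists with at least 5 measured genes, 32 in all, were tested against the other genes with limma's camera at its preset correlation of 0.01. Camera with an estimated correlation and fry, which does not compare a list with other genes, were alternatives.

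The genes named in the text follow a rule that was also fixed then. It takes up to 12 genes per direction with non-overlapping groups, filled where too few pass the threshold by those with the smallest unadjusted p and a log2 change of at least 0.5. It adds 4 members of each list past its threshold, up to 2 members of each other list, and 12 stress, cold and clock genes whatever their values. Of those 12 genes, FKBP5, TSC22D3, PER1, NR1D1 and DBP are not analysed here, since no probe set in the annotation carried their symbol alone. The rule gave 88 genes, and the text prints part of them. Symbols of the lists were matched to current symbols, and a synonym was accepted only where it is no gene's current symbol and belongs to a single gene. This stricter matching replaced a looser one after list values had been seen, because the looser one joined different genes. It changed the members of 5 lists, and 0 list calls differed.

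The alternatives were a filter on the dimmest 25% or 50% of probe sets, an intensity trend in the variance, a robust form of it, array weights, median centring, quantile and cyclic loess normalization, other thresholds, other ways to treat several probe sets of a gene, leaving out each array, and each of the 6 ways to match samples into pairs as a block. The robust form was not run for the lists, since camera has no such option. The estimate of array weights stopped before its convergence tolerance was reached. Leaving out the after 2 and before 6 arrays together was added after the data were seen.

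The scripts were first tested on simulated data made from the means and residual spread of the 12763 probe sets. In 2 groups of 3 without a block, 13.4% of 67 probe sets with a simulated log2 change of 1 passed the threshold, 91.0% of 67 with a change of 2 and 98.5% of 66 with a change of 3. Of the 140 calls 5 were false. With matched pairs as a block and the smaller residual spread of that fit, 95.5% of 67 with a change of 1 passed. Of the 213 calls of that fit 16 were false. A list shifted by 0.5 gave a camera adjusted p of 1.64e-11, and an adjusted p of 0.0419 with an estimated correlation. The simulated genes were drawn independently of each other, while the estimated correlation on the real arrays was 0.24 for immediate-early genes. This simulation therefore does not show how camera at its preset correlation of 0.01 performs on correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.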

Results

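Blood cell RNA of Sanhe heifers was profiled before and after severe cold, to follow gene expression in response to it. The labels describe 3 hours outdoors at -32 °C followed by 15 hours in a cowshed at 5 °C, and they do not state when in this sequence the later blood was drawn. There were 3 arrays after cold and 3 before, from 3 animals. Each array gave an intensity for 12763 probe sets, and values below are log2 intensities.

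No single gene passed the test for a difference between blood cells after and before cold. With limma, 0 of 12763 probe sets passed an adjusted p of 0.05, and the smallest adjusted p was 1.00 (0.999983 before rounding). At an unadjusted p under 0.05 there were 63 probe sets, 4 higher and 59 lower after cold, where chance alone gives 638. All 63 differed by at least 1.5-fold. The groups did not overlap in 559 probe sets, or 4.38%, and chance gives 10%. Both chance values take the 6 arrays as independent. Since each animal has an array in both groups, spread between animals stays in the error of this fit and can lower such counts. The shortfall therefore does not show that cold changed nothing. A change of at least 1.5-fold, whatever its p, was seen in 898 probe sets, 29 higher and 869 lower, while over all probe sets 6687 had a higher and 6076 a lower mean after cold. Differences of group means ran from -1.24 to 0.95, against a median SE of 0.33. Without the after 2 array, 1787 probe sets had an unadjusted p under 0.05, and without the after 3 array 5 did. Array weights gave 662, of which 95 were higher and 567 lower. A block for matched samples gave 24 to 1168 over the 6 possible matchings. The highest, for 1-4, 2-6, 3-5, lay above the 638 of chance, with 250 higher and 918 lower, and the labels do not say which matching is true.

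The named genes with non-overlapping groups are given as values, since each had an adjusted p of 1.00 in limma. Higher after cold were PHF13, a chromatin protein, with 8.18 ± 0.29 against 7.46 ± 0.19 (SD, n = 3 in each group), and PNMA1, with 6.78 ± 0.11 against 6.18 ± 0.05. The Mediator subunit gene MED25 differed by 0.57 ± 0.25 (SE), the tubulin-binding TPPP by 0.63 ± 0.30 and the adenosine receptor ADORA2B by 0.53 ± 0.27. These 5 were the only genes in that direction that met the rule, while 131 met it in the other. Lower after cold was LPL, the lipase that splits triglycerides of lipoproteins, with 5.74 ± 0.46 against 6.73 ± 0.56. CALCRL, a receptor for calcitonin-family peptides, differed by -0.88 ± 0.34 and SPTLC1, a subunit of the enzyme that starts sphingolipid synthesis, by -0.87 ± 0.35. NOL8 (-1.06 ± 0.42), DDX52 (-0.93 ± 0.38) and SDAD1 (-0.90 ± 0.37) are nucleolar proteins of ribosome assembly, and MRPL30 (-0.90 ± 0.37) belongs to the mitochondrial ribosome. NOL8, DDX52 and SDAD1 were lowest on the after 3 array, at 6.58, 5.99 and 5.83. On after 2 they were at 8.27, 7.49 and 7.27, just under their lowest values before cold of 8.32, 7.57 and 7.35. LAMTOR3, a scaffold of lysosomal signalling, differed by -0.87 ± 0.34, the complement regulator CFI by -0.75 ± 0.31 and the acetyltransferase NAT1 by -0.79 ± 0.33. HSPBAP1 differed by -0.82 ± 0.33 and GRAMD1C by -0.98 ± 0.40.

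**Figure D1:**
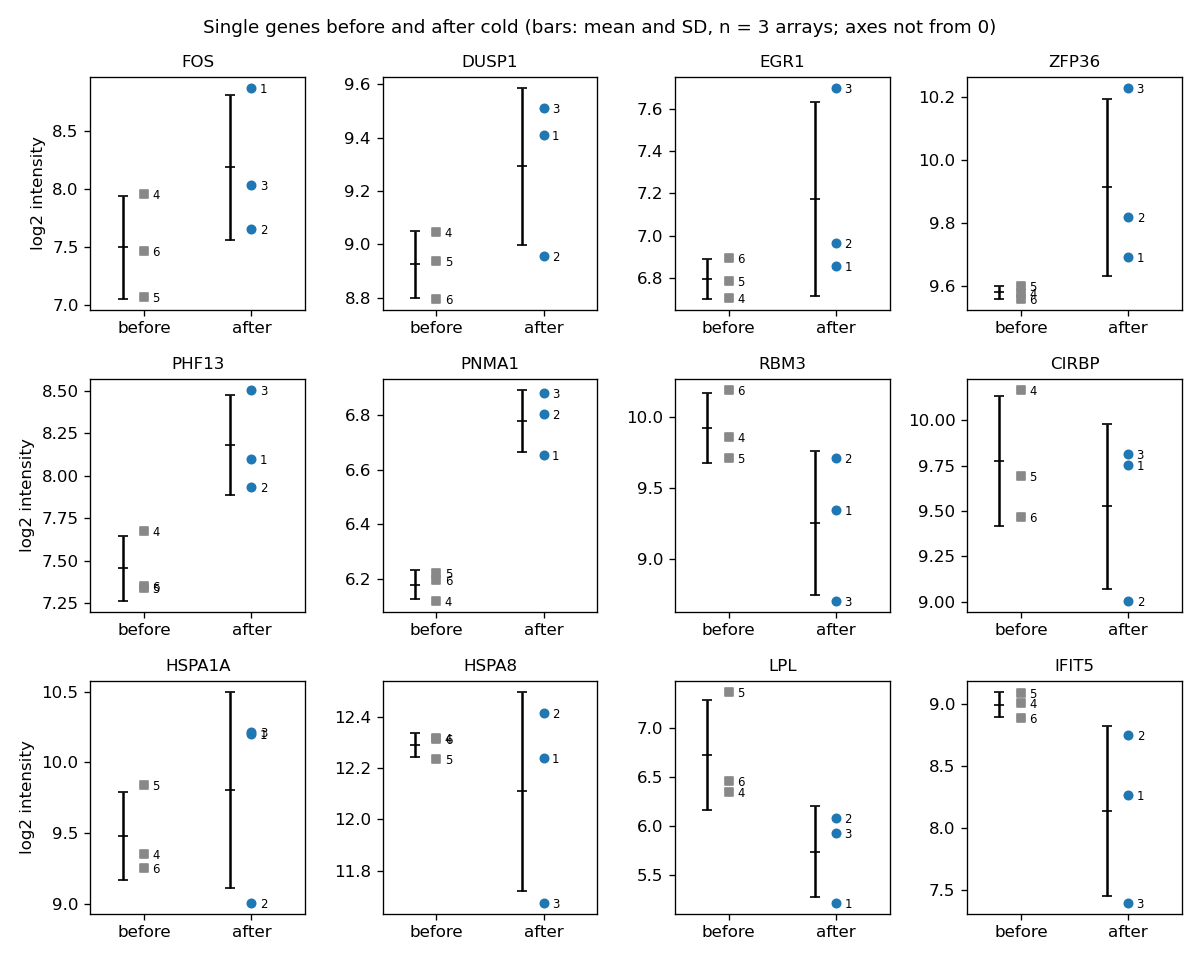
Log2 intensity of 12 named genes on each array, with squares for the 3 arrays before cold and circles for the 3 after, labelled by array number; bars show the mean and SD of each group. PHF13, PNMA1, ZFP36, LPL and IFIT5 have groups that do not overlap, RBM3 and DUSP1 overlap narrowly, and the after 2 and after 3 arrays often lie at opposite ends of their group.

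Among the 33 gene lists, immediate-early genes, which cells switch on within minutes of a stimulus, were higher after cold as a list. Of 17 measured members, 16 had a higher mean after cold, with a median log2 change of 0.16 (camera, adjusted p = 0.00785). The call was lost with an estimated correlation (adjusted p = 0.935), with fry (adjusted p = 0.949), with array weights (adjusted p = 0.0586) and without the before 5 array (adjusted p = 0.0647). The median was 0.30 without the after 2 array, 0.11 without the after 3 array and 0.11 with array weights. FOS, a subunit of the AP-1 transcription factor, was at 8.18 ± 0.62 after and 7.50 ± 0.44 before (SD, n = 3 in each group). The phosphatase DUSP1 differed by 0.37 ± 0.26 (SE), the transcription factor EGR1 by 0.38 ± 0.30 and ZFP36, which promotes decay of cytokine mRNAs, by 0.33 ± 0.26. MCL1 was the member with a lower mean, by -0.05 ± 0.42. No member passed the threshold, over all probe sets or adjusted over the list alone. On each array, the median deviation of the members from their means was 0.11, -0.17 and 0.25 after cold and -0.06, -0.15 and -0.27 before. Over the 6 arrays these values had a Pearson correlation of -0.89 with the first principal component described below, which does not follow the groups. This is not particular to the list. Some lists that did not pass had stronger ones, such as glycolysis (-0.97), clock genes (0.97) and NF-kappaB targets (-0.92), and others weaker ones, such as T cell markers (0.03).

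The other 31 lists tested did not pass the camera threshold, and in none of the 33 lists did a member pass it, over all probe sets or adjusted over the list alone. No list passed with an estimated correlation or with fry, whose test for changes in either direction also called none. Median, mean and test differed in sign for the lists of MHC class I presentation, fatty acid oxidation, the unfolded protein response, oxidative stress defence, apoptosis and hypoxia.

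Of the stress lists, the cold-inducible RNA-binding and cold shock domain proteins had 2 of 5 members higher and a median of -0.25 (camera, adjusted p = 0.717). RBM3, an RNA-binding protein known for its induction in cooled cells, was at 9.25 ± 0.51 after and 9.92 ± 0.25 before cold. Its relative CIRBP differed by -0.25 ± 0.33 (SE) and YBX1 by -0.31 ± 0.27. Without the after 2 array the CIRBP value was 0.0095. Heat shock chaperones were split into 12 higher and 12 lower members, with a median of -0.0079 (adjusted p = 0.918). The inducible HSPA1A differed by 0.33 ± 0.38 and the constitutive HSPA8 by -0.18 ± 0.28. HSP90AA1 differed by -0.16 ± 0.35, with another of its probe sets at 0.14 ± 0.39, and HSPH1 by 0.02 ± 0.49. Signs of HSPA8 and HSP90AA1 turned without the after 3 array, and that of HSPH1 without after 2 (-0.51), before 4 (-0.13) or before 5 (-0.12). Glucocorticoid-induced genes had 7 of 9 members higher (median 0.07, adjusted p = 0.604), among them the decoy receptor IL1R2 at 0.41 ± 0.24. Circadian clock genes had 2 of 5 higher (median -0.05, adjusted p = 0.918), with RORA at -0.50 ± 0.46, or 0.010 without the after 3 array. The unfolded protein response had 9 of 16 higher (median 0.05, adjusted p = 0.918), with the chaperone DNAJB9 at -0.69 ± 0.33. Oxidative stress defence had 10 of 23 higher (median -0.02), hypoxia-induced genes 10 of 18 (median 0.02) and apoptosis genes 8 of 14 (median 0.08), each with an adjusted p = 0.918.

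Of the immune response lists, NF-kappaB targets had 14 of 17 members higher with a median of 0.18 (camera, adjusted p = 0.448). Inflammatory cytokines and chemokines had 9 of 14 higher (median 0.09, adjusted p = 0.918), with the cytokine genes IL1B at -0.83 ± 0.48 (SE) and TNF at 0.35 ± 0.33, or -0.17 with array weights. Interferon-stimulated genes were split into 14 higher and 16 lower (median -0.03, adjusted p = 0.717). IFIT5, an interferon-induced RNA sensor, differed by -0.86 ± 0.36 and PARP9 by -0.76 ± 0.39. Toll-like receptor and pattern recognition genes had 4 of 11 higher (median -0.20, adjusted p = 0.645), with the kinase IRAK4 at -0.49 ± 0.31. In MHC class II presentation 5 of 10 were higher (median -0.0025, adjusted p = 0.918), with the protease CTSS at -0.68 ± 0.30. In MHC class I presentation 7 of 15 were higher (median -0.0076, adjusted p = 0.918). Adhesion and trafficking genes had 9 of 14 higher (median 0.06, adjusted p = 0.876).

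Markers of blood cell types did not pass the threshold either. Eosinophil, basophil and mast cell markers had 0 of 6 members higher with a median of -0.26 (camera, adjusted p = 0.165). They included ALOX15, a lipoxygenase of eosinophils, at -0.82 ± 0.55 (SE) and RNASE6 at -0.54 ± 0.38. Without the after 1 array this list had an adjusted p = 0.0313 at the preset correlation, and over all 6 arrays 0.935 with an estimated one. Monocyte markers had 3 of 10 higher (median -0.16, adjusted p = 0.604), with the scavenger receptor MSR1 at -0.66 ± 0.28, and without the after 3 array an adjusted p = 0.00473 at the preset correlation, against 0.935 over all 6 arrays with an estimated one. The monocyte median was -0.39 without the after 3 array and 0.10 without the before 5 array. B cell markers had 7 of 8 higher (median 0.13, adjusted p = 0.433), with CXCR5 at 0.41 ± 0.25 and POU2AF1 at 0.46 ± 0.28. T cell markers had 10 of 18 higher (median 0.03, adjusted p = 0.876), gamma delta T cell markers 2 of 5 (median -0.26, adjusted p = 0.876), and NK and cytotoxic markers 9 of 12 (median 0.17, adjusted p = 0.876). The NK and cytotoxic median was -0.37 with array weights and -0.11 without the after 1 array. With array weights the T cell median was -0.26. GZMB, a granzyme of killer cells, differed by -0.59 ± 0.27. Neutrophil markers had 7 of 10 higher (median 0.15, adjusted p = 0.876), platelet genes 3 of 7 (median -0.08, adjusted p = 0.918) and red cell genes 8 of 9 (median 0.09, adjusted p = 0.645). The granule protein genes of immature granulocytes had 4 measured members and were not tested, and ANXA3 among them differed by -0.63 ± 0.28.

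Of the metabolic and growth lists, oxidative phosphorylation had 60 of 74 members higher with a median of 0.12 (camera, adjusted p = 0.162). It passed without the after 2 array (adjusted p = 0.00216) and without the before 5 array (adjusted p = 0.00064), with medians of 0.27 and 0.22, while without the before 6 array the adjusted p was 0.910. These used the preset correlation, and with an estimated correlation, 0.52 for this list, the adjusted p over all 6 arrays was 0.935. Its members with the smallest p ran the other way, COX7A2L at -0.52 ± 0.29 (SE) and ATP5PB at -0.61 ± 0.35. Cytosolic ribosomal proteins had 36 of 61 higher (median 0.03, adjusted p = 0.842) and glycolysis 15 of 19 (median 0.10, adjusted p = 0.717). Fatty acid oxidation and lipid handling had 13 of 22 higher (median 0.08, adjusted p = 0.918), with the acyl-CoA synthetase ACSL3 at -0.78 ± 0.40 and the carnitine carrier SLC25A20 at 0.46 ± 0.25. Thermogenesis and hormone signalling genes had 7 of 9 higher (median 0.08, adjusted p = 0.886). Cholesterol biosynthesis had 6 of 14 higher (median -0.08, adjusted p = 0.662), with the pathway enzymes HMGCS1 at -0.76 ± 0.34 and MSMO1 at -0.71 ± 0.31, and without the after 3 array an adjusted p = 0.0395 at the preset correlation, against 0.935 over all 6 arrays with an estimated one. Cell division genes had 10 of 24 higher (median -0.07, adjusted p = 0.717), with NUSAP1 at -0.95 ± 0.49.

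**Figure D2:**
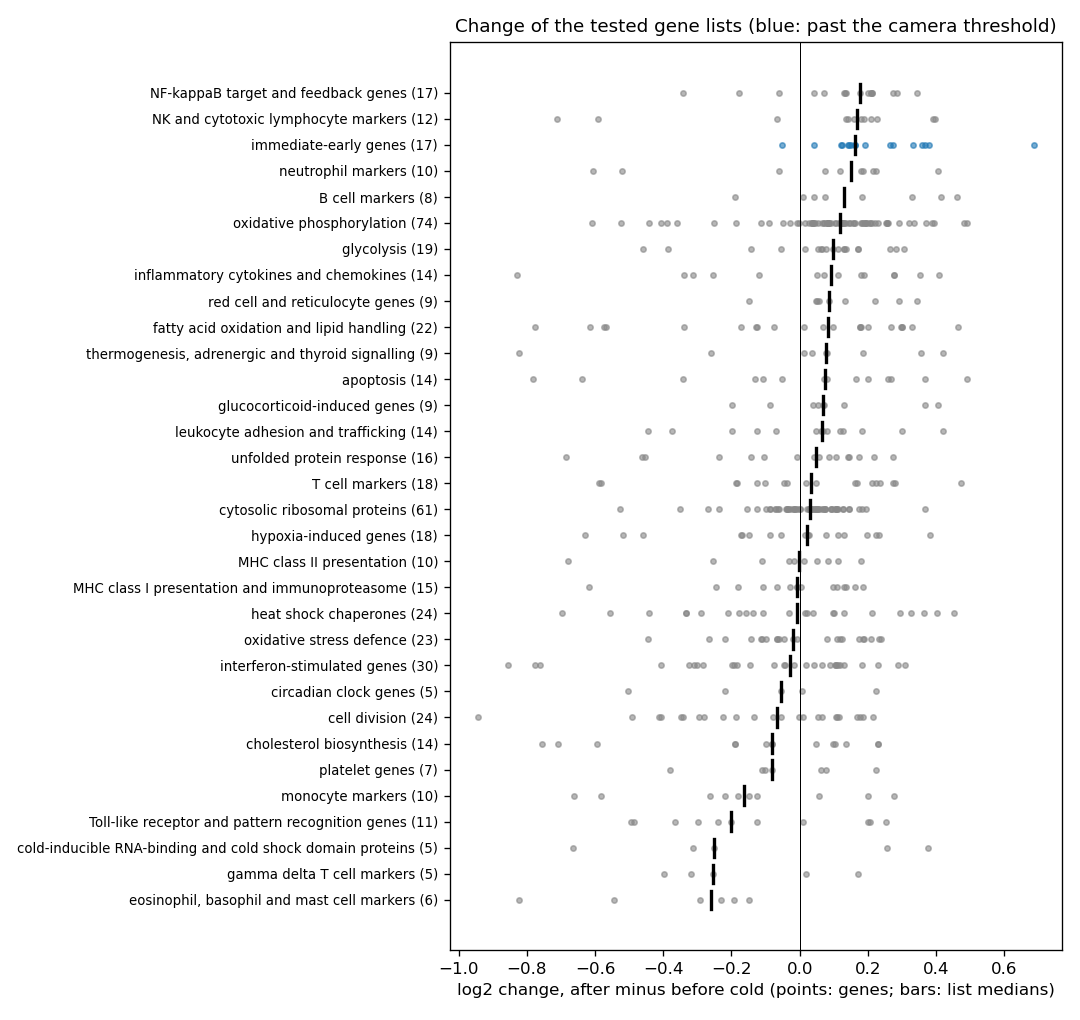
Log2 change, after minus before cold, of each measured member (points) and the median (bars) of the 32 tested gene lists, with the number of members in brackets. Immediate-early genes, in blue, passed the camera threshold with 16 of 17 members above 0, and lost the call with an estimated correlation (adjusted p = 0.935) and with fry (adjusted p = 0.949).

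The arrays differed among themselves along a direction that did not follow the groups. The first principal component held 68.4% of the variance, with scores of -23.3, 52.1 and -63.2 after cold and -1.31, -16.3 and 52.0 before. The after 2 and before 6 arrays correlated at 0.995 across probe sets, and 4 probe sets differed between them by over 2-fold. The after 2 and after 3 arrays of a single group correlated at 0.874, and 4867 probe sets differed by over 2-fold. The mean score after cold minus that before was -23.0. Across probe sets, which are not independent, the change after cold had a Pearson correlation of -0.65 with the loading on this component. This correlation follows from that score difference and the component's share of the variance, and is not separate evidence. The same component separated arrays within each group.

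**Figure D3:**
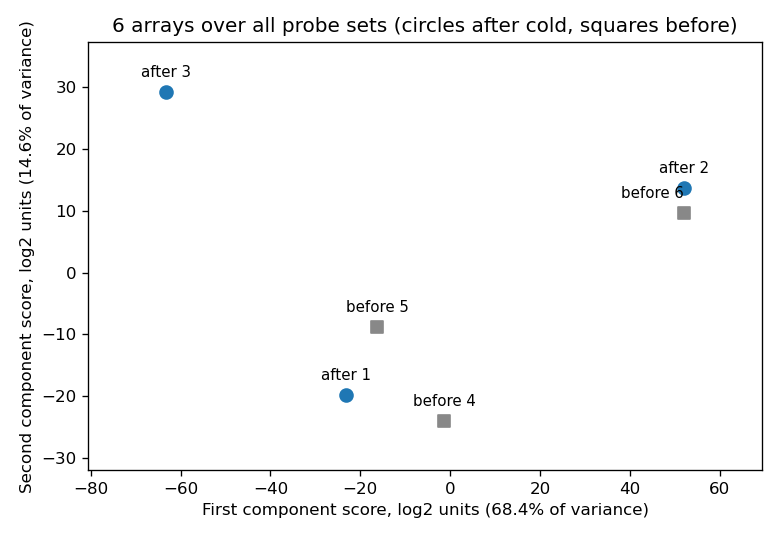
Scores of the 6 arrays on the first and second principal components of all probe sets, in log2 units, with circles after cold and squares before. The after 2 and before 6 arrays lie together at 52.1 and 52.0, and the groups are not separated.

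Probe sets for MHC genes, which differ in sequence between animals, had very low values on some arrays and high values on others. A BOLA-DQB1 probe set was at 2.74 on the after 2 array and 2.86 on before 6, and between 11.4 and 12.1 on the other 4. Another BOLA-DQB1 probe set was at 3.32 on after 3 and 3.82 on before 5, and between 11.8 and 12.3 elsewhere. A range over 4 log2 units was seen in 9 of 30 MHC probe sets and in 6 of the other 12733 (Fisher's exact test, two-sided, p = 2.87e-21). Several of these probe sets measure the same gene, so they are not independent.

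**Figure D4:**
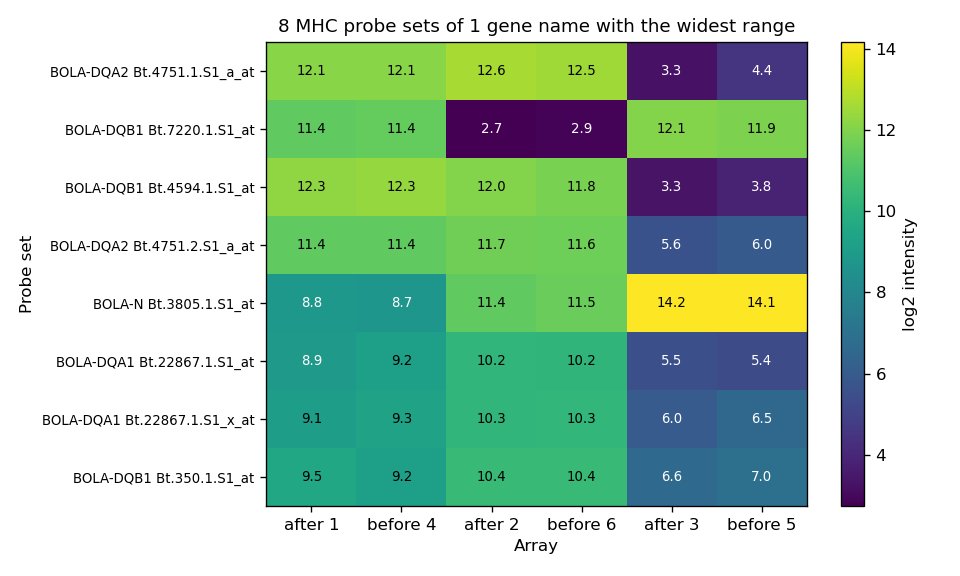
Log2 intensity of the 8 MHC probe sets of 1 gene name with the widest range, in rows, on the 6 arrays, in columns ordered by likeness of these values. A BOLA-DQB1 probe set is at 2.74 and 2.86 on after 2 and before 6, and the BOLA-N probe set is at 14.2 and 14.1 on after 3 and before 5.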

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

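The fit without the after 2 and before 6 arrays together was chosen after the data were seen, and the other settings before. With limma, 0 probe sets passed an adjusted p of 0.05 in each setting run, and the count became 63 only with an unadjusted p, with or without a 1.5-fold minimum. The 63 at an unadjusted p under 0.05 became 27 without the dimmest 50%, 662 with array weights, 109 with median centring, 100 with quantile and 102 with cyclic loess normalization, and 1234 without the after 2 and before 6 arrays. Leaving out each array in turn gave 5 (without after 3) to 1787 (without after 2). The block for a matching of samples gave 33 (1-4, 2-5, 3-6), 1168 (1-4, 2-6, 3-5), 24 (1-5, 2-4, 3-6) and 656 (1-5, 2-6, 3-4), and the remaining matchings stayed within 1.5 times. Of the 1168, 250 were higher and 918 lower after cold, and of the 662 with array weights 95 were higher and 567 lower, against 4 and 59 with neither. The labels do not name the true matching. The cause of these shifts was not tested, except that leaving out arrays lowers their number. What dim signal limits was not tested, since no measure of background was used.

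The 1 list past the threshold became 0 with array weights, with an estimated correlation and with fry, 2 without the after 2 and before 6 arrays, and 1 to 3 on leaving out each array. The immediate-early list had an adjusted p of 0.0586 with array weights, 0.935 with an estimated correlation, 0.949 with fry, and 0.0175 to 0.0647 on leaving out each array, lost without before 5. Without the after 2 and before 6 arrays, the list past the threshold beside it was oxidative phosphorylation (adjusted p = 0.0216).

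Of 733 list values under alternatives, 61 had the opposite direction, 0 of them past the threshold, and 12 lists kept their direction throughout. Adjusted p of lists that reversed with array weights were 0.977 for heat shock chaperones, 0.754 for clock genes and for monocyte markers, 0.857 for Toll-like receptor genes, 0.993 for MHC class II, 0.210 for T cell, 0.205 for NK and cytotoxic markers, 0.959 for platelet genes, 0.977 for fatty acid oxidation, 0.994 for oxidative stress defence and for apoptosis and 0.846 for hypoxia. NK and cytotoxic markers reversed without the dimmest 25% (0.972) or 50% (0.887), apoptosis without the dimmest 50% (0.969) and with quantile normalization (0.918), fatty acid oxidation with quantile normalization (0.941), and heat shock chaperones with the mean of all probe sets of a gene (0.975). MHC class I reversed with fry (0.949), with the block 1-4, 2-6, 3-5 (0.923) and without the after 2 and before 6 arrays (0.956).

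Lists that reversed when some array was left out had these ranges of adjusted p: heat shock chaperones 0.407 to 0.942, clock genes 0.494 to 0.883, cytokines 0.134 to 0.937, Toll-like receptor genes 0.229 to 0.981, MHC class II 0.529 to 0.991, MHC class I 0.407 to 0.935, T cell markers 0.257 to 0.884, gamma delta T cell markers 0.134 to 0.799, NK and cytotoxic markers 0.407 to 0.879, monocyte markers 0.00473 to 0.906, neutrophil markers 0.134 to 0.993, platelet genes 0.407 to 0.884, glycolysis 0.134 to 0.884, fatty acid oxidation 0.733 to 0.967, thermogenesis 0.700 to 0.948, the unfolded protein response 0.624 to 0.980, oxidative stress defence 0.799 to 0.980, apoptosis 0.669 to 0.986, cell division 0.134 to 0.980 and hypoxia 0.799 to 0.935. The low end for monocyte markers, without after 3, kept the direction.

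Of 88 named genes, 70 kept their sign in each setting, and none passed the threshold in any. None turned under median centring, quantile or cyclic loess normalization. With array weights the log2 change became 0.58 for ERAP2, -0.0083 for ICAM3, -0.0080 for IER3, 0.16 for ITGA4, 0.24 for ITGB3, 0.017 for NFE2L2 and -0.17 for TNF. Without the after 2 and before 6 arrays it was -0.24 for HSPH1. Leaving out each array gave -0.064 to 0.53 for BHLHE40, -0.33 to 0.72 for BPI, -0.41 to 0.0095 for CIRBP, -1.46 to 0.055 for ERAP2, -0.092 to 0.54 for GNG11, -0.49 to 0.053 for HSP90AA1, -0.33 to 0.039 for HSPA8, -0.51 to 0.43 for HSPH1, -0.12 to 0.44 for IFI30, -0.98 to 0.010 for RORA, -0.87 to 0.13 for TARP and -0.56 to 0.12 for TRGC6. The cause of these reversals was not tested.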

Other observations

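The tests of the matching of arrays, of cell shares on the main component and of pair differences were chosen after the results they bear on had been seen. The splits of the samples and the test of genomic span among ribosomal protein and oxidative phosphorylation genes were set before their values were seen. However, the relation of genomic span to the component over all genes was known by then. Splitting those genes into the 2 lists came after.

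If arrays 1 and 4, 2 and 6, and 3 and 5 are taken as pairs, which rests on the values and not on the labels, some genes differed in the same direction in each pair. They were chosen after their values were seen, from the 15 per direction with the largest smallest difference, and none passed the threshold in limma with the pairs as a block (adjusted p = 0.492 for each). DGAT2, an enzyme of triglyceride synthesis, was higher after cold by 0.71, 0.87 and 0.56, the cannabinoid receptor gene CNR2 by 0.54, 0.64 and 0.47, and the serotonin transporter gene SLC6A4 by 0.48, 0.44 and 0.58. ALOX15 differed by -0.77, -0.96 and -0.75, HPGD, which inactivates prostaglandins, by -0.86, -0.51 and -2.27, and RBM3 by -0.52, -0.48 and -1.003. The immediate-early list had median differences of 0.11, 0.08 and 0.52 in these pairs. With the pairs as a block its camera adjusted p was 0.0230, and with an estimated correlation the adjusted p was 0.942. A difference of at least 0.3 in the same direction in each pair was seen in 205 probe sets, 84 higher and 121 lower. With the sign of pair 1-4, 2-6 or 3-5 turned, the counts were 29, 80 and 20. These 4 arrangements are too few for a test at 0.05. Across probe sets, the differences in pairs 1-4 and 3-5 had a Pearson correlation of 0.50. Those in pair 2-6 had 0.09 with 1-4 and 0.17 with 3-5. Turning 1-4 or 3-5 therefore lowers the count whether cold or the main component lies behind their likeness.

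With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. All 10 gave at least the real 0 probe sets past the threshold, and the highest of the others was also 0. For an unadjusted p under 0.05, 7 of 10 splits gave at least the real 63, and the highest of the others was 4611. For gene lists, 8 of 10 gave at least the real 1, and the highest of the others was 9. The split with 4611 put after 1, after 3 and before 5 against the rest. It keeps arrays 3 and 5 and arrays 2 and 6 each on one side. Each of the 6 splits above 63 keeps 2 of the pairs 1-4, 2-6 and 3-5 in this way. A count this far above the real one points to a structure of the samples other than the groups. If these pairs share an animal, such splits compare animals and not times of sampling. The splits that part each of these pairs gave 63 (the real one), 4, 36 and 6 probe sets. Their lists past the threshold numbered 1 (the real one), 0, 2 and 0. These splits are too few for a test at 0.05.

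Arrays resembled an array of the other group in the matching 1-4, 2-6, 3-5. Over 30 MHC probe sets the root mean square difference was 0.32 log2 units in this matching, and the next best was 4.83 times as large. Over the other 12733 probe sets the margin was narrow, with 0.44 in this matching and 0.51 in the next best. Across all probe sets before 5 correlated at 0.947 with after 3 and at 0.965 with after 1. A range over 4 log2 units was seen in 30% of MHC probe sets against 0.047% of the others. A technical difference acting on all probe sets alike would not by itself give this MHC pattern. Animals that differ in MHC sequence can give it with or without such a difference, so the test does not exclude one. For the likeness of arrays over the other 12733 probe sets it decides nothing. A candidate explanation is that each such pair of arrays comes from 1 animal. By the design text each of the 3 animals was sampled at both times, so 1 of the 6 matchings is true. The MHC values, at 0.32 here against 1.55 to 3.10 in the other matchings, argue against those others. The labels do not name the animals, and the matching was noticed in the same values.

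The component that held 68.4% of the variance was not explained by the groups. Its loading had a Spearman correlation of 0.42 with the genomic span of 6327 genes. Among 2500 genes outside the ribosomal protein and oxidative phosphorylation lists, with spans of 2174 to 17515 bp, it was 0.21. The change after cold had a correlation of -0.28 with span, and the differences in pairs 1-4, 2-6 and 3-5 had -0.32, 0.03 and -0.23. RNA quality or labelling that depends on gene length is a candidate explanation. It would act on the length of the mRNA, for which genomic span, with its introns, is only a rough stand-in. The test set for this took 135 ribosomal protein and oxidative phosphorylation genes together and gave 0.0058 (approximate SE 0.086), below its bound of 0.1. That bound was wrong, since 53 of the 61 ribosomal protein genes had means over 13, near the top of the scale, with a median SD over the arrays of 0.086, and the 74 oxidative phosphorylation genes, with 0 means over 13, gave 0.40 (approximate SE 0.12) by themselves, so the test decides nothing and this explanation stays open. Different shares of T cells, B cells and myeloid cells cannot be told apart from other causes here: the 4 list medians of the difference between after 2 and after 3 spanned 0.524 log2 units, with SDs of 0.66 to 0.80 among members. The intensity distributions of the arrays went with this component. After 2 and before 6, with the highest scores, had log2 medians of 7.49 and 7.44, and SDs over probe sets of 1.89 and 1.89. After 3, with the lowest score, had a median of 7.25 and an SD of 2.04, and the other arrays lay between. What lies behind this relation was not tested. No label follows this component, so no explanation from the study's groups was tested.

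Probe sets lower after cold by at least 0.5 log2 units in pairs 1-4 and 3-5 numbered 918, and those higher numbered 83. Their position on the main component is a candidate explanation, since the arrays of pair 2-6 share a place on it (score difference 0.045). In pair 2-6, 75.9% of the higher ones were also higher, against 58.5% of all probe sets, and 53.9% of the lower ones lower, against 41.3% of all. Median differences there were 0.15 (SD 0.24) for the higher and -0.02 (SD 0.19) for the lower ones, against 0.04 for all. Compared with all probe sets, the shares and medians of both sets lay on the side of the other pairs. Most members fell short of 0.5 in pair 2-6, but picking them by the other pairs favours a smaller difference there. The SD is that of single probe sets and not the error of a median. A shared difference and the position on the component cannot be told apart, since pair 2-6 is 1 array per group and its probe sets are not independent. The bounds were restated after the shares were seen, at first from 45% to 55%, which 53.9% would have met, and later by asking the median of a set to differ from that of all by more than its SD; before that, 75.9% counted against the position on the component. Cold exposure itself stays open as a biological explanation, and so does a difference in handling between the times of sampling, which would coincide with the groups.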
